A study of Danio rerio and Caenorhabditis elegans with 4 samples.

How the data were processed

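The series measured N4-acetylcytidine (ac4C), an acetylated form of cytidine in RNA, by RNA immunoprecipitation sequencing (RIP-seq) in wild-type zebrafish (Danio rerio) and the worm Caenorhabditis elegans. RNA bound by an anti-ac4C antibody was sequenced beside an input library made without antibody. There were 4 libraries, 1 RIP and 1 input library for each species, and the groups were taken from the sample titles. The labels describe the material as cells of animal organs and name no organ, stage or sex. Per the labels' protocols, total RNA was made into stranded mRNA libraries with unique molecular identifiers. Whether reads were collapsed by those identifiers is not given in the sources used here.

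The submitters' processing notes name HISAT2, StringTie and DESeq, with no version or role, and the genome builds danRer10 and WBcel235. The peak caller is not given in the sources used here. The deposited peak list of each species holds counts of RIP and input reads summed over each peak, a log2 fold of RIP over input, a p-value and a false discovery rate, per the file headers. All folds per peak are the authors' own values unless a ratio of counts is named. A peak can take several rows, 1 for each block, and its values are repeated on each. Blocks were therefore joined, and each peak was used once. Peaks of 1 bin span 25 bases. In such peaks the authors' log2 value equalled the log2 ratio of the deposited counts plus a constant. That constant was 2.95 in zebrafish, a factor of 7.71, and held within 0.001 in 1358 of 1360 such peaks with input reads. In the worm it was 3.30, a factor of 9.85, and held in 1221 of 1221. The factors equalled 185/24 and 128/13 to a relative error of 1.75e-07 and 3.62e-07. In longer peaks the authors' fold need not equal the scaled ratio of the summed counts, and can lie outside that ratio's counting interval. Both values come from the same reads, so the interval gives a scale and does not test their difference. At 125 bases, the 2 values were equal within 0.001 log2 units in 28 of 761 zebrafish and 22 of 724 worm peaks with input reads. Among peaks over 1000 bases with input reads, they were equal within 0.001 log2 units in 239 of 1146 in zebrafish and 0 of 11 in the worm. Among peaks of named genes and list members with input reads, the authors' fold lay outside the counting interval of the scaled ratio in 13 of 106 in zebrafish and 16 of 95 in the worm. The text gives both for some of these.

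The zebrafish list holds 220 peaks on 127 alternate contigs, and its chromosome 4 positions reach 78025465. Which zebrafish build the coordinates follow was left unsettled, because whether these contigs and positions belong to the build named in the notes could not be checked without a genome. Coordinates are printed 1-based as the files give them. Worm coordinates are taken to be on WBcel235. Zebrafish names were compared with a RefSeq gene table of assembly GRCz12tu, used for names and gene types only, in which 4517 of 4552 genes (99.2%) were found by current or older symbol. Worm gene IDs were found in a table of IDs and symbols for 4372 of 4495 genes (97.3%). No genome was used here, so base content, transcript length, exons and untranslated regions were not analysed.

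Each list holds enriched peaks alone, with no values for genes without a peak. The planned filter and ratios for whole gene tables therefore did not apply, and the plan's wording for a peak list was followed: numbers of peaks and genes, and the distribution of the authors' fold and p-value. A gene's fold was the mean of the authors' log2 values over its peaks, and its abundance the mean over its peaks of the log2 RIP and log2 input counts, each with 1 added. Both definitions were set after the files were seen. Gene lists of pathways, complexes and tissues, and ortholog pairs, were written before the data were examined. For a peak list the plan asked for the share of members with a peak; the percentile of the list's fold was given in addition. A list's median fold was placed among the medians of 10000 random lists with as many genes in each of 20 abundance bins. Percentiles at or below 2.5 or at or above 97.5 are called lower or higher, and lists with under 5 genes are given as values. These percentiles describe single libraries and test no condition. Tested on simulated data with lists of shifted genes, the procedure called 55% of zebrafish lists and 67.5% of worm lists at a shift of 0.5 log2 units. At a shift of 1 it called 95% and 100%, and at no shift 0% and 7.5%, with 40 lists simulated in each case among 4552 and 4495 genes. The simulated lists had a single size, larger than most of the real lists, and were shifted upward only. They were ranked among fewer random lists than the real ones. These rates therefore do not give the sensitivity for shorter lists or for downward shifts.

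Ortholog pairs were compared with Fisher's exact test and with Pearson's r and Spearman's rho, each with 100000 permutations of the pairs, all two-sided. The plan named the 2 correlations for the pairs and did not name Fisher's test. Benjamini-Hochberg adjustment was made over the pair sets. Exact 95% Clopper-Pearson intervals were made for the ratio of a peak's summed counts and multiplied by the species' constant. They cover counting error only and are too narrow for a peak of several bins where a read was counted in more than 1 bin. Peaks with 0 input reads point to such counting. Those of rbm47 and foxo1a had the same authors' fold, 1173.3, with 196 RIP reads over 175 bases and 224 over 200. Counts called reads here, the abundances and the read minimums are thus sums over bins and can rise with peak width. A peak with 0 input reads was given a lower bound against a floor of 3 input reads. That bound leaves out the counting error of its RIP reads and is too high where they were counted in several bins. The named genes were, by a rule fixed before the data were examined, the 10 genes with the highest peak fold among peaks with at least 20 reads and a gene symbol, up to 2 members at each end of a described list, the ac4C writer and its adaptor, the 5 genes with most input reads, and 3 ortholog pairs at each end. No gene was named for a low fold, since every authors' fold in the lists was above 1. The scaled ratio of summed counts was below 1 in 6 zebrafish peaks and 0 worm peaks. Alternatives covered the count minimum, the pseudocount, the fold and false discovery rate thresholds, the scaling, gene type, the matching of random lists and the use of a gene's highest peak. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.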

Results

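ac4C RIP-seq was carried out on zebrafish and on the worm C. elegans to ask whether this RNA modification is involved in evolution. Each species had 1 RIP library and 1 input library, so no value below has a replicate check. The deposited peak counts summed to 2419428 RIP reads and 7836153 input reads in zebrafish, and to 23923618 RIP reads and 23180281 input reads in the worm. These sums cover listed peaks alone, can count a read in more than 1 bin, and are not library depths, which are unknown here.

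In zebrafish, 7279 peaks lay in 4552 genes, of which 2899 (63.7%) held 1 peak. Among genes with a symbol, the 10 highest folds came from peaks with 0 input reads. They lay in epb41b, which encodes a protein of the red cell membrane skeleton, npas1, tmem53, the glycosyltransferase gene extl2, the RNA-binding protein gene rbm47, the forkhead factor gene foxo1a, the Rh blood group gene rhd, the somatostatin receptor gene sstr5, the sterol synthesis gene msmo1 and tpst2, which encodes a tyrosylprotein sulfotransferase. Against the floor of 3 input reads, the scaled ratio of the summed counts was at least 593.5 in npas1 (231 RIP reads; chromosome 15, 8426397 to 8426571). It was at least 575.555 in foxo1a (224 RIP reads; chromosome 15, 3372021 to 3372220) and at least 503.6 in rbm47 (196 RIP reads; chromosome 1, 19353973 to 19354147). The bound was at least 493.3 in sstr5, 477.9 in tmem53, 400.8 in rhd, 372.569 in extl2, 354.583 in msmo1, 226.1 in tpst2 and 92.5 in epb41b. These bounds leave out the counting error of the RIP reads. With it, the lower 95% limit was 478.857 in npas1, 464.2 in foxo1a, 405.7 in rbm47 and 71.4 in epb41b. The build of the zebrafish coordinates was not settled.

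At the other end of abundance, the 5 zebrafish genes with most input reads had folds of 1.08 to 1.55 in their main peaks. The main peak of tpma, a muscle tropomyosin gene, held 168147 RIP and 874530 input reads and had a fold of 1.54, which was 6.95% of RIP and 11.16% of input reads in peaks. Folds were 1.26 for the plasma apolipoprotein gene apoa1b, 1.14 for the main peak of the fast muscle myosin gene myhz1.1 (44149 RIP and 298005 input reads), 1.08 for the fast muscle troponin gene tnnt3b and 1.55 for ptmab. The gene of the ac4C-writing acetyltransferase, nat10, held 2 peaks. Their folds were 6.12 (156 RIP and 203 input reads; chromosome 18, 38225596 to 38228437) and 6.94 (18 and 20 reads). The gene of its adaptor, thumpd1, held 4 peaks with folds of 7.27 to 42.4, the highest from 11 RIP and 2 input reads with a counting interval of 9.25 to 394. For the thumpd1 peaks at 7.27 and 25.5 the scaled ratio of the counts was lower, 5.38 and 14.01.

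The authors' median fold over the zebrafish peaks was 5.07, with quartiles of 3.19 and 9.58, and 6815 peaks (93.6%) had a fold of at least 2. These folds include the authors' scaling by a factor of 7.71. Before it, RIP reads exceeded input reads in 2181 peaks (29.96%), and 940 peaks had a read ratio of at least 2 with 1 read added to each. With at least 200 reads, 4359 peaks were left, and 3895 of them had a fold of at least 2. The authors' deposited table gave p-values of at most 9.86e-07 except for 11 peaks in 8 genes, where they reached 0.5. Among these 8 were hoxc5a and hoxc9a, members of a homeobox cluster, and filip1l, pabpc1a and srsf7b. For the hoxc9a peak the authors' fold was 3.04 and the scaled ratio of its 147 RIP and 1544 input reads was 0.734.

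In the worm, 6734 peaks lay in 4495 genes, of which 3100 (69.0%) held 1 peak. Of the 10 named genes with the highest folds, 4 had 0 input reads in the peak, and their bounds were at least 187 in mpz-1, a gene for a protein with many PDZ domains, 144 in gldi-10, 91.897 in lin-25 (chromosome V, 12650275 to 12650299) and 85.3 in the noncoding RNA gene rncs-1 (chromosome X, 1012321 to 1012345). The mpz-1 and gldi-10 peaks span 75 and 50 bases, so their counts are sums over bins and their bounds may be too high. By the authors' fold lin-25 (1498.7) was highest of the 4 and mpz-1 (1017) lowest. The C-type lectin gene clec-223 had a fold of 385 (169 RIP and 5 input reads) and the twinfilin gene twf-2 a fold of 371 (290 and 8 reads). The spliced leader RNA genes sls-1.10 and sls-2.10 each had 30 RIP reads and 1 input read, a ratio of 295 with a counting interval of 49.1 to 12051. Their counts are identical, so they cannot be read as independent loci. The fold was 290 in sao-1. In the aquaporin gene aqp-11, with 3968 RIP and 90 input reads, it was 257, and the scaled ratio of the counts was 434.

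The gene with most input reads in the worm was grl-23, which belongs to a family of hedgehog-related ground-like proteins. Its peak on chromosome V, 12575215 to 12576894, held 15346870 RIP reads, 64.1% of RIP reads in all peaks, and 5014716 input reads, 21.6% of the input. The authors' fold was 62.4 and the scaled ratio of the counts 30.1. The blocks of this peak add up to 1250 bases, so its counts are sums over many bins. The main peak of its relative grl-25 (chromosome III, 8962295 to 8963613) had a fold of 66.9, while other grl-25 peaks had folds of 1.31 to 2.74. The main peaks of the cuticle collagen genes col-2 and col-84 and the chaperone gene hsp-90 had folds of 1.58, 1.70 and 1.75, and scaled count ratios of 1.63, 1.39 and 1.84. A further hsp-90 peak, with 34 RIP and 48 input reads, had a fold of 6.89. The worm homolog of the ac4C writer, nath-10, had no listed peak, which gives no fold for it.

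Worm ribosomal RNA held peaks on chromosome I in 2 copies of rrn-1.1 (18S) and in rrn-3.1 (26S), although the labels describe mRNA libraries. Each rrn-1.1 copy held 12 peaks. The highest lay at 15063258 to 15063357 in one copy, with 806 RIP and 1202 input reads and a fold of 18.9, and at 15070455 to 15070554 in the other, with 804 and 1211 reads and a fold of 18.6. The scaled ratio of these counts was lower, 6.60 and 6.54. The copies share near-identical counts, so they cannot be read as independent loci. The 15 peaks of rrn-3.1 had a median fold of 3.84 and a highest fold of 10.98. By scaled count ratio the order was the other way, with 4 rrn-3.1 peaks from 7.25 to 10.3 above both. Peaks in the 5S genes rrn-4.2, rrn-4.3 and rrn-4.4 on chromosome V had folds of 16.9, 16.5 and 17.3. The first 2 had near-equal counts (113 and 110 RIP reads, 66 input reads each), so these 2 copies cannot be read as independent loci either.

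**Figure D1:**
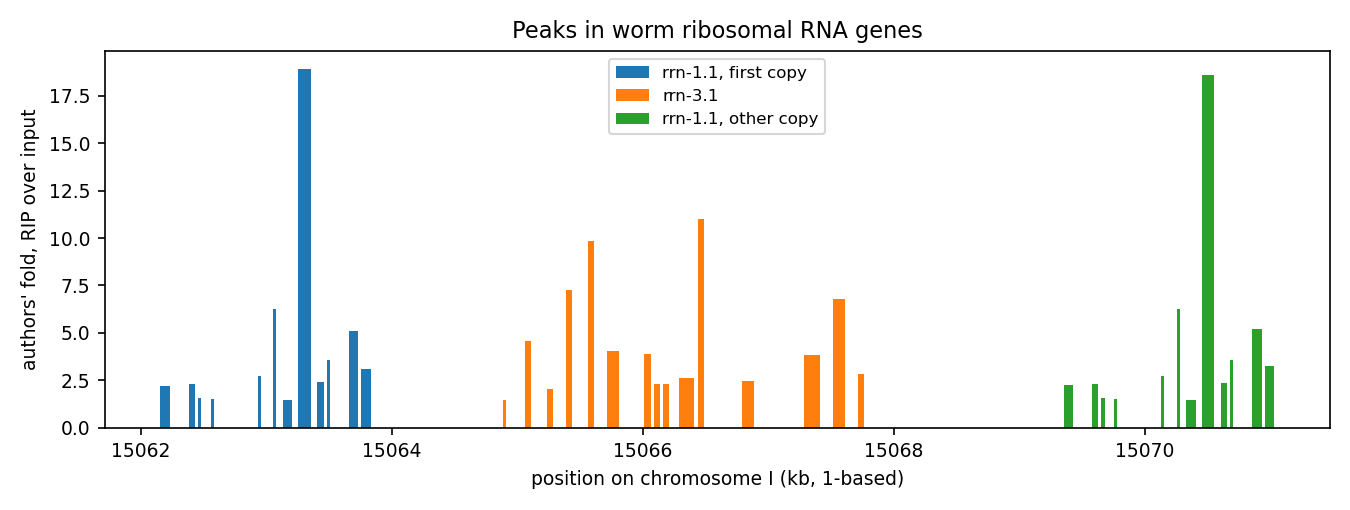
Peaks in worm ribosomal RNA genes on chromosome I; the x axis is the position in kb, bar width is the span of a peak, and the y axis is the authors' fold of RIP over input. The tallest bar in each copy of rrn-1.1 stands at 18.9 and 18.6, above the 10.98 reached in rrn-3.1; scaled ratios of summed counts, not drawn, reach 6.60 in rrn-1.1 and 10.3 in rrn-3.1.

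The median fold over worm peaks was 5.05, with quartiles of 3.06 and 9.72, and 6253 peaks (92.9%) had a fold of at least 2. The worm folds include a scaling factor of 9.85. Before it, RIP reads exceeded input reads in 1621 peaks (24.07%), and 592 peaks had a read ratio of at least 2. With at least 200 reads, 4272 peaks were left, of which 3791 had a fold of at least 2. The highest p-value in the authors' deposited table was 9.87e-07.

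Listed peaks with more input reads had lower folds in both species. In 4 equal groups of zebrafish peaks, from fewest to most input reads, the median log2 fold was 3.53, 2.70, 2.28 and 1.45. In the worm it was 3.54, 2.40, 1.88 and 1.61. Across genes, Spearman's rho of fold and input reads was -0.69 in zebrafish and -0.60 in the worm, where it was -0.37 among peaks with at least 200 reads. Input reads are the denominator of the fold, the lists leave out peaks below the authors' threshold, and genes are not independent replicates.

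**Figure D2:**
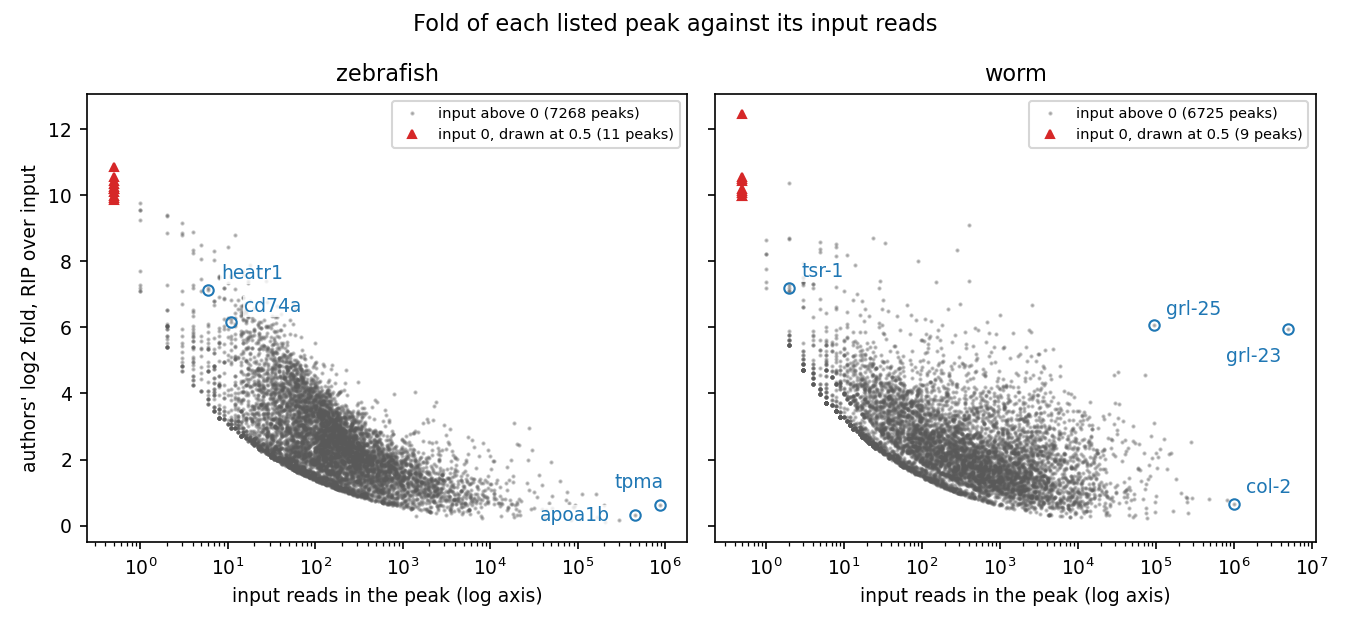
Each listed peak of zebrafish (left) and worm (right), with its input reads on a log x axis and the authors' log2 fold of RIP over input on the y axis; triangles are peaks with 0 input reads, and circles mark named peaks. The lowest listed folds drop along a curved edge as input reads rise, and grl-23 and grl-25 lie above other worm peaks of like abundance, at 5.96 and 6.06.

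Gene lists fixed in advance asked which pathways and tissues the peaks came from. In zebrafish, muscle genes had the lowest median fold, 1.85 over the 18 of 44 genes with a peak. The troponin gene tnnt2a and the calcium channel gene ryr1b led them with mean folds of 6.42 and 4.95, and the myosin heavy chain gene myhz2 (1.16) and tnnt3b (1.08) were lowest. Cytosolic ribosomal protein genes had a median of 1.93 over 23 of 86, from 11.1 in rpl35a and 4.22 in rps21 to 1.35 in rpl7a and 1.23 in rpl36. Nuclear genes of oxidative phosphorylation had a median of 2.96 over 31 of 106, from 61.5 in atp5mf to 1.46 in cox6b2 and 1.42 in atp5l, all of them subunits of the respiratory chain or ATP synthase.

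Muscle lay at percentile 0.02 of its matched random lists, oxidative phosphorylation at 0.11 and cytosolic ribosomal proteins at 0.315. The other zebrafish lists called lower were mitochondrial ribosomal proteins (median fold 3.28, 15 genes, percentile 0.06), liver and plasma proteins (3.27, 19 genes, 0.08), proteasome (2.53, 13 genes, 0.44), connective tissue and collagens (3.61, 35 genes, 1.095) and translation factors (3.05, 30 genes, 1.84). They ranged from mrps2 (37.04) to mrpl38 (2.04), from the fetuin gene ahsg1 (10.4) to apoa1b (1.26), from psma1 (8.47) to psmd1 (1.48), from col19a1 (89.01) to thbs4b (1.81) and from eef1da (14.1) to eef1b2 (1.53). No zebrafish list was higher, and 8 of 23 were lower, where chance gives 1.15 outside the limits in either direction. With random lists matched on input reads per base, an alternative chosen after seeing the data, cytosolic ribosomal proteins moved to percentile 32.1, translation factors to 15.9, liver and plasma proteins to 10.5 and proteasome to 9.475, none of them lower. Mitochondrial ribosomal proteins (6.55), translation factors (5.65) and liver and plasma proteins (3.75) lost the call at 200 reads or more, and connective tissue lost it with matching on input reads (4.3), with a pseudocount of 5 (4.15) and with the highest peak of each gene (21.55). Translation factors stayed lower in 5 of 10 alternatives.

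The other zebrafish lists lay within the range of random lists, although pancreas and gut were lower with a gene's highest peak (percentile 1.675) and glycolysis without peaks overlapping an opposite-strand peak (2.4), both added after the data were seen. Immune cell genes were nearest the top, at percentile 93.8 with a median fold of 11.4 over 6 genes. They ran from the antigen presentation gene cd74a (71.5; 95 RIP and 11 input reads) and the macrophage gene mpeg1.2 (19.99) to lcp1 (5.15). Genes of neurons and glia (27 genes), eye (31), pancreas and gut (9), skin (11) and red blood cells (6) also held peaks. Their medians were 3.50, 4.75, 3.87, 2.56 and 5.19, at percentiles 11.19, 14.3, 3.625, 4.295 and 9.68. In the ovary and germ cell list 1 of 26 genes had a peak, ddx4 (7.32). The testis and cilia list had 4 of 29 (13.8%), led by the dynein gene dnah9 (33.9). None of 29 yolk and egg coat genes had a peak. Over all protein-coding genes the share with a peak was 16.65%, and no list's share was tested against it. The list of RNA methylation and acetylation enzymes and related proteins, with 10 of 34, lay at percentile 39.9. It ran from the m6A writer gene mettl3 (22.03) and thumpd1 (16.95) to igf2bp3 (3.13) and zc3h13 (2.75). Nucleolar and ribosome assembly factors lay at 50.6 with a median of 4.38 over 32 genes, led by heatr1 (141; 105 RIP and 6 input reads). Median folds were 3.77 for heat shock proteins (29 genes, percentile 12.4), 3.07 for glycolysis (19 genes, 3.725), 5.18 for tRNA synthetases (8 genes, 44.6) and 7.26 for the V-ATPase (6 genes, 57.25). They were 4.95 for histones (5 genes, 45.4), 4.24 for hox genes (6 genes, 23.7) and 3.50 for the chaperonin (5 genes, 22.6). The hox median includes hoxc5a and hoxc9a, which have p-values of 0.25 to 0.5 and, in their highest peaks, scaled count ratios of 0.689 and 0.734.

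In the worm, cytosolic ribosomal protein genes had the lowest median fold, 2.56 over the 62 of 83 genes with a peak. They ran from rpl-41.2 and rps-13 (13.1 each, on 35 and 14 reads in all) to rps-19 (1.36) and rpl-11.2 (1.34). Muscle genes had a median of 2.68 over 29 of 35. The myosin light chain gene mlc-2 (8.36) and the titin-like ttn-1 (7.91, the mean of 28 peaks) were highest, and the myosin gene myo-3 (1.56) and the troponin gene tnt-2 (1.34) lowest. Cuticle collagen genes had a median of 2.96 over 76 of 176, from dpy-10 (105, with a scaled count ratio of 144; 4576 RIP and 312 input reads) and col-115 (29.5) to sqt-2 (1.28) and rol-8 (1.26). Histone genes had a median of 2.63 over 8 of 82, from his-17 (17.6) to hil-3 (1.62).

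Worm cytosolic ribosomal proteins, cuticle collagens and histones lay at percentile 0, below all of their 10000 matched random lists, and muscle lay at 0.065. Translation factors lay at 0.89 (median fold 2.78, 18 genes, from eif-3.J at 11.22 to eef-1A.1 at 1.45) and glycolysis at 1.595 (4.79, 8 genes, from pfk-1.2 at 59.1, on 2 input reads, to ipgm-1 at 1.99). No worm list was higher, and 6 of 19 were lower, where chance gives 0.95 outside the limits. Matched on input reads per base, cytosolic ribosomal proteins moved to percentile 33.4, translation factors to 13.65, muscle to 10.5 and cuticle collagens to 6.275, and none was then lower. Translation factors also lost the call with matching on input reads (3.1), and glycolysis with a pseudocount of 5 (2.95) or without peaks overlapping an opposite-strand peak (2.55).

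Other worm lists lay within range. Sperm genes were nearest the top at percentile 95.1, with a median fold of 15.2 over 8 of 98 genes, from spe-8 (97.47, on 3 input reads) and ssq-4 (44.3, on 2 input reads) to the major sperm protein gene msp-59 (7.36) and spe-48 (6.80). Germline genes lay at 74.9 (7.88 over 11 of 48), led by the helicase gene glh-4 (17.8) and the Notch receptor gene glp-1 (15.8). Neuron (36 genes), intestine (56) and innate immunity (49) lists had medians of 4.32, 4.59 and 5.41, at percentiles 12.2, 4.42 and 18.2. The intestine and innate immunity lists share members and are not independent, with clec-223 and clec-142 highest in both. The syntaxin gene unc-64 led the neuron list at 51.0. Nucleolar and ribosome assembly factors had peaks in 21 of 25 genes, with a median of 5.09 at percentile 80.6, led by tsr-1 (148; 30 RIP and 2 input reads) and rrp-8 (27.12). With a gene's highest peak in place of the mean, an alternative chosen after seeing the data, they lay at 97.6, and matched on input reads per base at 97.9, both higher. The proteasome had a median of 3.31 over 15 genes (percentile 2.845), led by rpn-8, whose fold was 35.5 and scaled count ratio 101. It was lower with pseudocounts of 0.1 (2.05) and 5 (1.625), and in 2 alternatives chosen after seeing the data, the highest peak of a gene (1.475) and folds from summed counts (1.85). Oxidative phosphorylation had a median of 3.97 over 13 genes (3.31), and was lower matched on input reads per base (2.475); the intestine list was lower with a gene's highest peak (percentile 1). Median folds were 4.81 for mitochondrial ribosomal proteins (19 genes, percentile 38.005), 3.55 for tRNA synthetases (13 genes, 7.335), 6.22 for nuclear hormone receptors (23 genes, 31.8), 4.15 for heat shock proteins (25 genes, 33.3) and 7.45 for the V-ATPase (5 genes, 65.2). None of the 6 yolk genes had a peak.

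**Figure D3:**
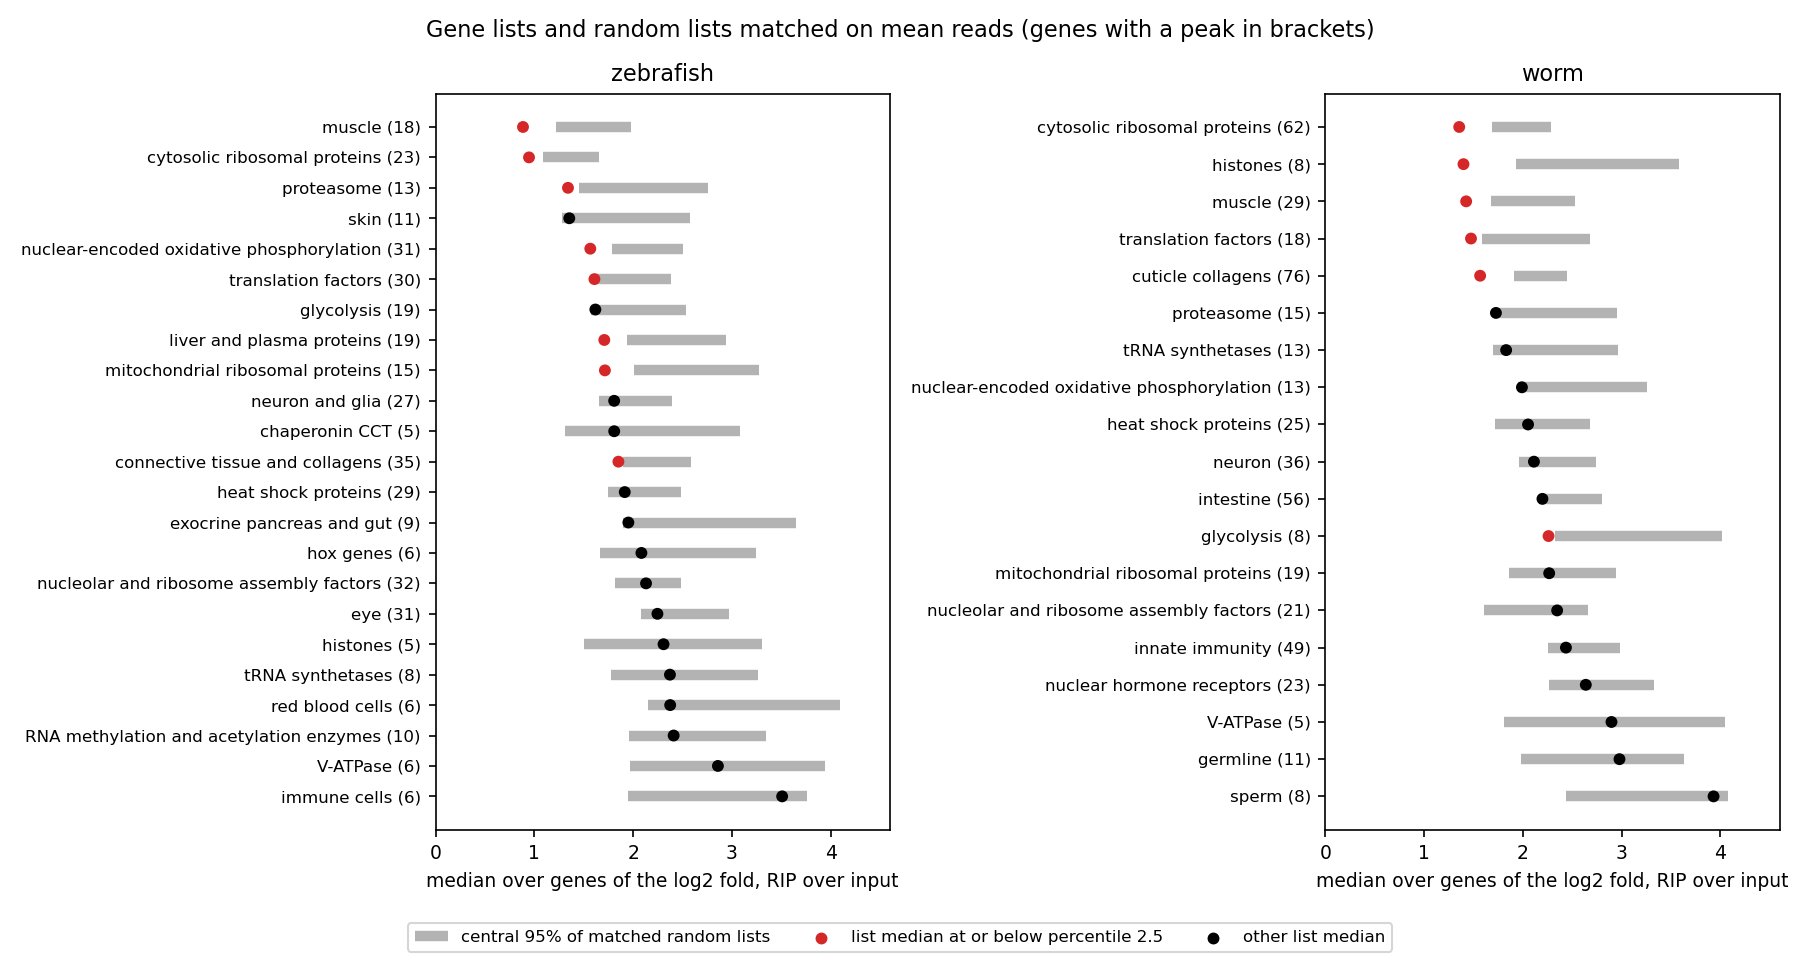
Median log2 fold of each gene list (points) in zebrafish (left) and worm (right), with grey bars for the central 95% of random lists matched on mean reads; the number of genes with a peak is in brackets, and red points lie at or below percentile 2.5. Muscle, cytosolic ribosomal proteins and translation factors are red in both species, and no point lies above its bar.

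The species were then compared over ortholog pairs with 1 gene chosen per species. A gene can have a second copy outside the pairs, so a pair without a peak can have one there: psmd11b had none, while its copy psmd11a had a peak with a fold of 7.16. Of 184 pairs fixed in advance, 179 had both genes in the name tables, and 51 had peaks in both species, where 50.1 are expected if peaks fell independently. A further 29 pairs had a peak in zebrafish alone and 61 in the worm alone, and 38 had none (odds ratio 1.096, two-sided Fisher's exact p = 0.877, adjusted p = 1). The highest summed folds belonged to the spectrin pair sptbn1 and unc-70 (log2 2.09 and 4.98), the cohesin pair smc1al and him-1 (5.44 and 1.49) and the replication helicase pair mcm7 and mcm-7 (2.65 and 3.89). The lowest were the ribosomal protein pairs rpl36 and rpl-36 (0.30 and 0.98), rps19 and rps-19 (0.95 and 0.44) and rps10 and rps-10 (0.78 and 0.65).

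Across the 51 pairs the folds of the species showed no detectable relation, with Pearson's r of 0.09 (permutation p = 0.523, adjusted p = 0.866) and Spearman's rho of 0.06 (permutation p = 0.679, adjusted p = 0.8185). Spearman's coefficient was -0.12 without ribosomal protein genes and -0.08 with at least 200 reads. Genes are not independent replicates, and every listed log2 fold is positive, so a share of pairs with the same sign has no content. Ribosomal protein pairs had a peak in the worm in 54 of 70 pairs and in zebrafish in 21 of 70. Among 57 other conserved pairs, which leave out the ribosomal, proteasome, chaperonin and tRNA synthetase classes, 25 had peaks in both species against 20.8 expected (odds ratio 3.87, exact p = 0.0259). After adjustment over 7 sets of pairs p was 0.181, which did not pass 0.05. A gene needs reads to hold a listed peak, and expression in the species was not adjusted for. Of the 5 pairs left out, 3 hold a gene taken here to be the same under another name, a link the name tables do not give: hsp-90 for daf-21, arf-1 for arf-1.2 and hars for hars1. With these added after the data were seen, 52 of 182 pairs had peaks in both species (51.5 expected, p = 1), among them hsp90ab1 and hsp-90 (log2 0.65 and 1.44), and Spearman's rho was 0.066. The other conserved pairs were then 26 of 59 (exact p = 0.0279, adjusted p = 0.195).

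**Figure D4:**
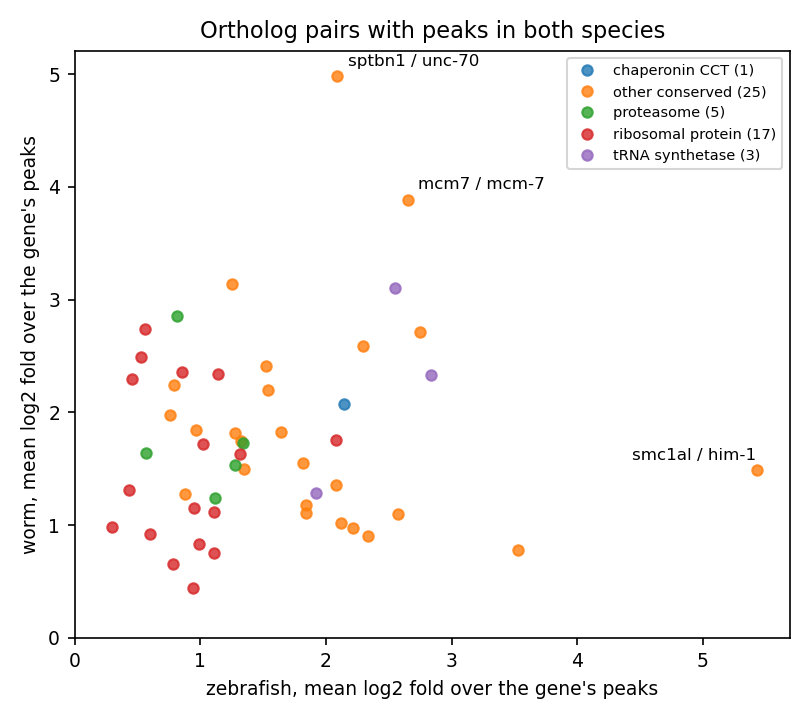
Mean log2 fold over a gene's peaks in zebrafish (x axis) and worm (y axis) for the 51 ortholog pairs with peaks in both species, coloured by class. Spearman's rho is 0.06, and ribosomal protein pairs sit toward the lower left.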

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

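Alternatives marked here as added were chosen only after the data were seen: the authors' scaling left out, opposite-strand or wide peaks left out, a gene's highest peak, matching on input reads per base, folds from summed counts, and ortholog pairs with renamed genes. Alternatives for lists and pairs used 2000 random lists and 20000 permutations, matching per base also left out peaks over 1000 bases, and summed-count folds left out peaks with no input reads. Peak numbers fell most with at least 200 reads (zebrafish 4359, worm 4272; with fold of at least 2, 3895 and 3791) and with a false discovery rate of at most 0.001 and fold of at least 4 (4562 and 4135), since fewer peaks pass; at a fold of 4 alone the worm kept 4135. Peaks with fold of at least 2 numbered 1686 and 1575 after centring on the median peak, and 940 and 592 without the authors' scaling (added). Other settings kept both counts within 1.5 times. The number of zebrafish lists outside the random range was 5 instead of 8 with at least 200 reads and 4 with matching on input reads per base (added); the worm number ranged from 4 to 9 against 6. Over single lists and alternatives, the call was the same in 207 of 222 cases in zebrafish and 170 of 185 in the worm. In 13 and 7 cases a call was lost, and in 2 and 8 cases a list came to lie outside. Most lists, 15 of 23 and 13 of 19, lay within range to begin with. A call could be lost only among the 8 and 6 lists called lower, so the totals overstate how stable those calls are. Zebrafish muscle and oxidative phosphorylation stayed lower in 10 of 10 alternatives. Worm histones stayed lower in the 8 of 10 alternatives that could be run for them. The alternative that leaves out near-identical gene families removes the histone genes, so it could not test that list. The other missing alternative left under 5 histone genes, so the list was not tested there either. Spearman's coefficient between the species turned to -0.117 without ribosomal protein genes (p = 0.509) and -0.0786 with at least 200 reads (p = 0.627), and the cause was not tested. Spearman's coefficient of fold and input in the worm moved to -0.370 with at least 200 reads, and the cause was not tested. Not run were TMM scaling, which needs genes without peaks, matching on transcript length, sequence features, means over transcripts, and protein-coding genes alone in the worm, for which no genome or gene type was used here. No paired analysis was possible because each group holds 1 library. Depth limits the folds of peaks with few input reads: 11 zebrafish and 9 worm peaks had none.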

Other observations

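The tests of the grl family, of strand and of single lists below were chosen only after the pattern was seen; those on the number of lists kept were set before their results. The mitochondrial genome of the worm held 24 peaks in 18 genes, with a median log2 fold of 2.92. The highest, at 9618 to 9642, carries the gene ID WBGene00014470, for which no symbol was found. It held 268 RIP and 2 input reads, a ratio of 1319 with a counting interval of 361.7 to 10951. COX3, a subunit of cytochrome c oxidase, had a fold of 16.5 (2310 RIP and 4408 input reads), against a scaled count ratio of 5.16. Worm long noncoding RNA genes also held peaks, among them linc-30 with folds of 34.9 and 38.1 and linc-8 with 23.5. The 2 linc-30 peaks hold near-equal counts (87 and 86 RIP, 25 and 24 input reads), so they cannot be read as independent. These genes were chosen after their values were seen.

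The worm gene with most peaks was ttn-1, with 28, followed by the spectraplakin gene vab-10 with 16. In zebrafish cenpe, a kinetochore motor gene, ryr1b and the collagen gene col5a3b each held 13. Among wide zebrafish peaks, 1147 had blocks adding up to more than 1000 bases, up to 97107, against 11 in the worm. Of these widths, 43 in zebrafish and 9 in the worm were whole numbers of bins. Wide zebrafish peaks held a median of 325.5 reads, against 244.5 in narrower ones. In the worm the medians were 110592 and 411. The zebrafish widths therefore cannot be taken as the length covered by reads, and the numbers of wide peaks do not show a difference between the species.

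Low folds of gene lists formed the first pattern: 14 lists lay below random lists matched on mean reads and none above, and averaging of log folds over bins was argued against, since 14 of 14 stayed lower with folds from summed counts. Imperfect matching of expression was left undecided for the lists as a whole, since 6 of 14 stayed lower when random lists were matched on input reads per base. Imperfect matching may account for the place of cytosolic ribosomal proteins (percentile 32.1 in zebrafish, 33.4 in the worm) and translation factors (15.9 and 13.65), although matched on input reads the ribosomal lists stayed lower (1.625 and 0.1). It stayed open for zebrafish liver proteins (10.5) and proteasome (9.475) and worm muscle (10.5), cuticle collagens (6.275) and glycolysis (2.2). These lay between the limits of 2.5 and 10 or within 2 sampling errors of one. It also stayed open for zebrafish connective tissue (0, but 4.3 matched on input reads). For zebrafish muscle (0.4) the test could not decide. The peaks of its members tnnt3b and myhz2 held 204460 and 106150 input reads, against a 95th percentile of 2409.2 over zebrafish peaks. Genes in the same abundance bin can therefore hold far fewer reads. Imperfect matching was argued against for zebrafish mitochondrial ribosomal proteins (0.45) and oxidative phosphorylation (1.725) and worm histones (0.05). The listing threshold, transcript length and base content stay open for these lists and zebrafish muscle. A lower ac4C level in them was not tested.

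The grl-23 peak holds 64.1% of the worm RIP reads in peaks and formed the second pattern. The other 14 grl genes had a median fold of 3.92, at percentile 27.86 of matched random lists. This excludes nothing, since reads of relatives placed on grl-23 need not raise the relatives' own folds. Reads shared within the family and a technical origin of reads at that locus stay open. A high ac4C level of grl-23 RNA stays an open hypothesis without a second library.

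Worm peaks that overlapped closely on opposite strands had near-equal counts in most pairs, the third pattern. In 29 pairs that overlapped by at least 80%, the median absolute log2 ratio of RIP reads was 0.0249, against 2.26 when the same peaks were paired at random. This is consistent with counting without regard to strand, although the kit is stranded. In all 204 worm peaks (3.03%) overlapped an opposite-strand peak, and in zebrafish 14 (0.192%). Counts were compared in the 29 worm pairs alone, and the largest absolute log2 ratio of RIP reads among them was 1.94. Where the counts of a pair are near-equal, which of the strands carried the reads cannot be read from them. No biological explanation was tested.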
